A study of Mus musculus with 4 samples.

How the data were processed

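The series holds 4 droplet single-cell RNA sequencing libraries of orthotopic mouse pancreatic tumors, 2 from vehicle-treated and 2 from TCDD-treated mice. Per the labels' protocols, tissue was minced and digested with collagenase V (1 mg/mL, 37 °C, 30 min) and passed through strainers of 500, 100 and 40 µm. Live cells were enriched with a magnetic dead cell removal kit before library preparation. Sequencing used 50-cycle paired-end reads, and the labels state a depth of 100000 reads without saying per what. The submitters' processing notes name Cell Ranger 7.1.0 and the mm10 build. The annotation version, the cell-calling settings, whether intronic reads were counted and any doublet or ambient RNA removal are not given in the sources used here.

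For each library 2 of the deposited lists were used: the cell barcodes that passed filtering and the features, 8 files in all. The barcode lists hold 1 barcode of 16 bases per line with the suffix 1, and the feature lists hold a gene identifier, a symbol and a feature type. Neither holds a measured value. The matrices of UMI counts were not analysed here, so the planned tests of expression by cell type and of cell type shares were not run, and no doublets were called. The main comparison between the groups is therefore of the number of cell barcodes per library, which carries no information on UMI depth. Libraries were assigned to groups and numbered by their titles.

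Everything below was computed from those lists with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Barcodes per library were compared by a two-sided exact permutation test of the difference of means. Barcodes shared by each of the 6 pairs of libraries were counted by exact match. They were tested against the products of the library sizes by a chi-square statistic with 100000 Monte Carlo draws given the total. The size of the common barcode pool was estimated as the summed products divided by the summed overlaps. In 200 simulated sets of 4 libraries of the same sizes, this test was run with fewer draws. At a threshold of 0.05 it called 2.5% of the sets with no added overlap. It called 99% of those with 40 barcodes added to 1 pair, the vehicle libraries, where the data gave 47.65 expected. Smaller excesses were not tried. The mean pool estimate was 99.65% of the simulated pool. Barcodes 1 base apart were counted within and between libraries. All 30 pairs planted in a simulated library were found, which checks the counting only and not the rate ratio.

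Features were matched by identifier to GENCODE release M21, which is on GRCm38, the assembly that mm10 denotes. It matched 32235 of 32285 identifiers, and the symbol was also equal for 31502 of these. Coordinates are 1-based gene spans from M21, and an overlap means that 2 gene spans share at least 1 base, introns included. The other 50 identifiers are not in M21, so the features were not made from M21 alone. They have no coordinates here, so an overlap with any of them could not be scored. The lists of AHR, T cell and cell type marker genes, the tests of barcodes per library and of shared barcodes, and the rule for named genes were fixed before the data were examined. Without count matrices that rule allows any member of these lists to be named as present or absent. It allows another gene only if its feature type or symbol occurs in 5 or fewer features. No symbol stood on more than 3 identifiers, so that clause excluded no gene. The genes that overlap Foxp3 are outside the lists and were chosen after the overlap was seen.

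The alternatives were leaving out each library, leaving out barcodes found in several libraries, a log2 ratio, counting barcodes 1 base apart once, and a replicate block. For shared barcodes they were a match within 1 base, a match on the first 12 bases, and a pool size from the pairs within groups. For features they were distinct symbols and a match ignoring case.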

Results

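Single-cell RNA sequencing was carried out on pancreatic tumors grown in mice given either the dioxin TCDD or vehicle. TCDD is a persistent ligand of the aryl hydrocarbon receptor (AHR), a transcription factor that responds to environmental and dietary small molecules. The study's title places the question in the effect of such ligands on pancreatic cancer and on T cells. The tumors came from 7940b, a KPC line of mouse pancreatic cancer cells. These cells were injected into the pancreas of C57BL/6J mice, to which the line is syngeneic. TCDD was given at 10 µg/kg, in 1 dose a week over 2 weeks, with DMSO as the vehicle, and tumors were taken on day 19. The data used here comprised 4 libraries, 2 from the vehicle group and 2 from the TCDD group, all under 1 batch label. For each library, the list of cell barcodes and the list of genes that reads were counted against were used. The gene list does not say which genes were detected. The gene counts of each cell were not analysed here, so no expression level, cell type share or T cell state is reported for either group, and the UMI depth of the libraries is not known here.

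The first question was whether the genes through which a response to TCDD would be read were in the gene list of these libraries. A feature is an entry in the list of genes that reads were counted against. Its presence is set by that list and says nothing on expression in these tumors. The list held 98.52% of the protein-coding genes of GENCODE M21, so full counts below say little about the genes chosen. All 8 genes of the AHR list fixed before the data were examined had exactly 1 feature. They were Ahr itself, its dimerisation partner Arnt, the repressor Ahrr, the cytochrome P450 genes Cyp1a1, Cyp1a2 and Cyp1b1, the ADP-ribosyltransferase gene Tiparp, and the quinone oxidoreductase gene Nqo1. On the mm10 (GRCm38) build, Ahr (ENSMUSG00000019256) lay on chromosome 12 from 35497974 to 35535038 on the minus strand. Cyp1a1 (ENSMUSG00000032315), a classical AHR target that encodes a xenobiotic-metabolising enzyme, lay on chromosome 9 from 57687928 to 57703824 on the plus strand. Its relative Cyp1a2 (ENSMUSG00000032310) lay beside it on the minus strand, from 57676937 to 57683703. Cyp1b1 (ENSMUSG00000024087) lay on chromosome 17 from 79701537 to 79715061, and Tiparp (ENSMUSG00000034640) on chromosome 3 from 65528410 to 65555518. Of these 8 genes, Ahr was the one whose span overlapped another feature found in M21, 1 gene on the opposite strand.

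The T cell list was complete as well, with 14 of 14 genes at exactly 1 feature. It included the lineage genes Cd3e, Cd4 and Cd8a, the regulatory T cell genes Foxp3, Il2ra and Ctla4, and the ectonucleotidase gene Entpd1 (CD39). It also included the Th17 and type 3 cytokine genes Il17a, Il17f and Il22, and Ifng, Tbx21 and Gata3 of the Th1 and Th2 programs. Il17a (ENSMUSG00000025929) lay on chromosome 1 from 20730905 to 20734496, and Il22 (ENSMUSG00000074695) on chromosome 10 from 118204942 to 118210047. Neither span overlapped another feature found in M21. Foxp3 (ENSMUSG00000039521), the master regulator of regulatory T cells, lay on the X chromosome from 7573644 to 7595245. Its span overlapped 3 other genes of the list, 1 on the same strand and 2 on the opposite strand. They were Ppp1r3f, Flicr and Ccdc22, listed without regard to strand and named here after the overlap was seen. Gata3 likewise overlapped 1 feature on its own strand and 2 on the other, and Entpd1 overlapped 1 on its own strand. These 3 genes were the ones with a same-strand overlap among all 75 preset genes, counting features found in M21. Reads in such shared spans can be hard to assign to 1 gene, and how they were assigned is not given in the sources used here.

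The 17 cell type marker lists, which include a T cell list that shares Cd3e with the list above and a list for cycling cells, were also fully covered, with 54 of 54 genes at exactly 1 feature. They included Krt8, Krt18, Krt19 and Epcam of epithelial and tumor cells, Col1a1 and Pdgfra of fibroblasts, and Pecam1 and Cdh5 of endothelium. The myeloid markers included Adgre1 and C1qa of macrophages, Ly6c2 of monocytes and S100a8 of neutrophils. Prss2 and Cela1 of acinar cells and Ins1 and Ins2 of islets would mark residual pancreas. Over all lists, 11 of the 75 genes overlapped another feature found in M21, 10 of them on the opposite strand.

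All 4 libraries carried the identical list of 32285 genes, of 1 feature type (gene expression), so every comparison between them rests on the same genes. All 32285 identifiers were mouse Ensembl genes, so the list held no feature for Cre recombinase or a reporter that could separate injected tumor cells from host epithelium. Of these identifiers, 32235 (99.85%) were found in GENCODE release M21. Of the genes in that annotation, the list held 21702 of 22028 protein-coding genes and all 270 T cell receptor gene segments and pseudogenes. It held 427 of 432 immunoglobulin genes and pseudogenes, 5605 of 5854 lincRNA genes and 2955 of 2959 antisense RNA genes. Of 9941 processed pseudogenes it held 1, and none of the 2207 microRNA or 354 ribosomal RNA genes. The list was not made from M21 alone, so a single gene that it lacks was not necessarily filtered out. A release difference alone would hardly remove all 2207 microRNA genes while keeping 2955 of 2959 antisense RNA genes. These values argue against it as the only reason for the missing classes. The list held 13 symbols starting with mt-, but none of the 2 mitochondrial ribosomal RNA or 22 mitochondrial transfer RNA genes of M21. There were 32245 distinct symbols, because 38 symbols stood on more than 1 identifier.

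The number of cell barcodes did not separate the groups. The vehicle libraries held 13785 and 12732 cell barcodes, a mean of 13258.5 ± 744.6 (SD, n = 2). The TCDD libraries held 14633 and 13159, a mean of 13896.0 ± 1042 (SD, n = 2). The mean difference of 637.5 barcodes (TCDD 1.048 times vehicle) was smaller than the difference between the 2 vehicle libraries (1053) and between the 2 TCDD libraries (1474). A TCDD library exceeded a vehicle library in 3 of the 4 possible pairings, and the difference TCDD 2 minus vehicle 1 was -626. The two-sided exact permutation test gave p = 0.667, and with 2 libraries against 2 it could not go below 0.333. Without TCDD replicate 1 the difference changed sign, to -99.5. The labels do not say whether each library came from a separate mouse, so the spread between libraries may be technical. The number of barcodes also depends on tissue handling, on the cells loaded and on the cell-calling settings, which are not given here. It is not a direct count of recovered cells or a measure of tumor cellularity.

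**Figure D1:**
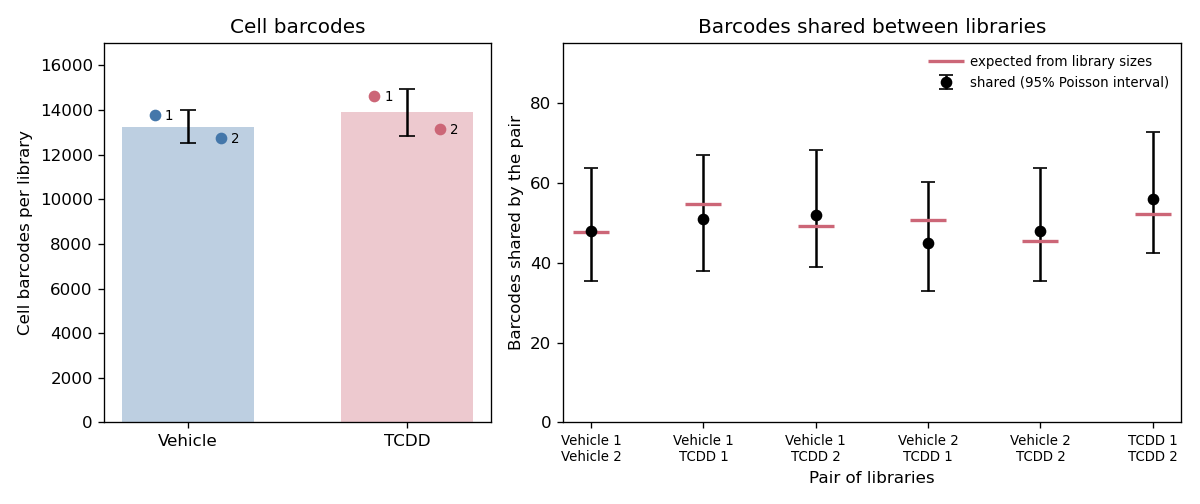
Left, cell barcodes per library (y axis, number) in the vehicle and TCDD groups, with points numbered by replicate, bars at the group mean and error bars of 1 SD (n = 2); the points of the groups interleave between 12732 and 14633. Right, barcodes found in both libraries of each of the 6 pairs (y axis, number), with 95% Poisson intervals, beside the number expected from the library sizes (horizontal marks); observed counts run from 45 to 56 and each interval contains its expected value.

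The lists were then compared to see whether the libraries were distinct. Any 2 libraries shared between 45 and 56 barcodes. The largest overlap, between the 2 TCDD libraries, was 0.426% of the smaller one. Between 1.03% and 1.16% of each library's barcodes occurred in any of the other libraries. The exact 95% binomial (Clopper-Pearson) intervals were 0.902% to 1.25% for vehicle 1 and 0.911% to 1.28% for vehicle 2. They were 0.868% to 1.202% for TCDD 1 and 0.987% to 1.36% for TCDD 2, and cover counting error only. The 300 overlaps over the 6 pairs did not detectably depart from the library-size products (chi-square 1.43, Monte Carlo p = 0.921). The Monte Carlo test redraws the overlaps and does not permute libraries. Expected counts ran only from 45.48 to 54.76, so the test says little on whether overlaps scale with library size. Pairs within a group shared 104 barcodes and pairs between groups 196, against 208.2 predicted for the latter from the former (exact binomial p = 0.624). If each library drew at random from 1 pool of barcodes, these overlaps put the pool at 3683422 barcodes (95% Poisson interval 3289346 to 4138533).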

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

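The difference in cell barcodes between the groups rested on single libraries. Leaving out each library in turn gave TCDD minus vehicle differences from -99.5 (without TCDD replicate 1) to 1374.5 (without TCDD replicate 2), with 111.0 without vehicle replicate 2 and 1164.0 without vehicle replicate 1. It was 628.5 without barcodes found in several libraries and 645.5 with barcodes 1 base apart counted once. The log2 ratio was 0.0669. With the replicate number as a block (paired by number) the difference stayed 637.5, with 848 and 427 within the 2 numbers and an exact sign-flip p = 0.5, the smallest that 2 pairs allow. Nothing in the labels says that equal numbers share a day or litter, and 2 pairs of single values cannot test it. The exact tests used cannot pass a threshold of 0.05 with so few libraries, so these p-values say nothing about stability. The test of shared barcodes stayed above the threshold in every alternative run, with p from 0.613 to 0.973. The number of preset genes with exactly 1 feature stayed 75 when case was ignored, a match that can add features but not remove them. The settings intended for gene expression (size factors, low-count filter, block and left-out libraries) were not run, because count matrices were not analysed here.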

Other observations

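The comparison of barcodes 1 base apart was planned before its result was seen. The tests of rare barcode endings, of repeated libraries and of close pairs and rare endings between the groups were chosen after the values were seen. The test over the 6 pairs of libraries was fixed before the data were examined. Its plan named index hopping and a library deposited more than once as its purpose. The cut-offs for reading it on either were written after the overlaps were seen.

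Some cell barcodes may be erroneous copies of another cell's barcode in the same library. Pairs of barcodes 1 base apart numbered 22 within libraries, against 1.34 predicted from the 4 such pairs found between libraries. The rate ratio was 16.4 (95% interval 5.58 to 65.6, exact binomial p = 3.02e-10). Interval and p treat all pairs as independent and cover counting error only. The vehicle libraries held 19 of the 22 pairs and the TCDD libraries 3, so the pooled ratio rests mainly on the vehicle libraries. In 21 of the 22 pairs the difference was C against T and in 1 it was A against G, all at positions 10 to 16 counted from 1 at the first base of the barcode. Of 3868 distinct 9-base barcode endings, 34 occurred no more than 2 times over all libraries, while the other 3834 had a median of 14 occurrences. Of the 40 barcodes with such a rare ending, 19 (47.5%, exact 95% interval 31.5% to 63.9%) had a barcode 1 base away in their own library. These 19 belong to the same 22 pairs, so they describe the pairs and are no separate evidence on their origin. In 17 of the 20 pairs with exactly 1 rare-ending member, that member had T where the other had C.

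Errors that turned 1 accepted barcode into another accepted one could give this rate of close pairs (rate ratio 16.4, pooled over libraries). They could arise in sequencing, amplification or bead synthesis. The 3 kinds of error cannot be separated without the reads, and which base differences the list of accepted barcodes permits is not known here. The other 21 rare-ending barcodes had no such neighbour and stay unexplained.

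Vehicle 1 and vehicle 2 held 8 and 11 of these close pairs, and TCDD 1 and TCDD 2 held 2 and 1. Rare-ending barcodes numbered 18, 13, 6 and 3 in the same order. The groups did not overlap in either count, but the two-sided exact permutation p was 0.333 for both, the smallest that 2 libraries against 2 can give, and 1 in 3 splits would separate as far by chance. Together the rare-ending barcodes made up 0.0737% of the 54309 barcodes, and counting close pairs once moved the difference between the groups from 637.5 to 645.5.

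Deposit of 1 library under more than 1 name was argued against, since the largest overlap of a pair was 0.426% of the smaller library. No excess of shared barcodes in some pairs was detected (p = 0.921 by the Monte Carlo test, not a permutation of libraries). The upper bounds on the ratio of observed to expected overlaps ran from 1.19 to 1.40. A small excess in a single pair therefore stays open. Index hopping that favours some pairs could leave such an excess. The lists hold only barcodes that passed filtering, so hopping that left barcodes below the filter could not be seen. The test therefore cannot decide on index hopping. Hopping that affects all pairs alike cannot be told from the size of the barcode pool. No biological explanation was tested for either pattern.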
